A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

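RNA was measured in exponentially growing cultures of the budding yeast Saccharomyces cerevisiae, strain BY4741, a haploid laboratory strain of mating type a. Per the labels, wild-type (WT) cells and upf1 mutant cells were grown in rich medium at 30 °C to an optical density of 0.5 and treated for 15 min with cycloheximide (CHX, 100 µg/ml), an inhibitor of translation elongation, or with its solvent dimethyl sulfoxide (DMSO). Each of the 4 groups had 2 replicates, called biological replicates in the series design, so 8 libraries were compared. Per the labels' protocols, total RNA from a hot phenol extraction was mixed with an external RNA standard, depleted of ribosomal RNA and made into strand-specific libraries. Groups and replicate numbers were taken from the sample titles.

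The deposited table gave a signal for 11993 features, a normalized read density per feature and library, with the authors' mean of each group beside it. Per the submitters' processing notes, Trim Galore, HISAT2 2.2.0, featureCounts 2.0.0 and DESeq2 were used with genome build R64. The annotation, the filters and the step that normalized the densities are not given in the sources used here. The deposited group means equalled the means of their 2 replicate columns to 5.4e-13, and the columns of single replicates were used throughout. In each library the values of 11986 features, all those above 0 in any library, were whole multiples of what 1 read is worth at a single feature length, within 0.001 reads, which gave back the reads per feature and 1 factor per library. These factors matched a scaling on the median snoRNA within 0.498%. A density is therefore a level against the 76 snoRNAs, the small nucleolar RNAs that guide the modification of ribosomal RNA, and a change of all snoRNAs would appear as an opposite change of everything else. No feature was named as an external standard. For protein-coding genes without introns the recovered length exceeded the coding length by a median of 188 nt, and 14.0% had exactly the coding length.

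Feature names were matched to the reference annotation of build R64, which gave 5976 protein-coding genes with coordinates. The remaining names gave 1650 XUTs, 1526 NUTs, 925 CUTs, 845 SUTs, 654 open reading frames outside the reference annotation, 295 tRNAs, 76 snoRNAs, 16 other non-coding RNAs, 15 pseudogenes, 9 rRNA features and 6 snRNAs. The non-coding classes XUT, NUT, CUT and SUT are given by name only, with no coordinates used here. Reads of near-identical copies, such as members of the PAU family or the tandem CUP1 genes, and of features that overlap on the same strand can be split or lost in counting, and values of such genes are uncertain.

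Recovered reads per library ranged from 9.09 M to 25.66 M. The median XUT had 7 to 54 reads per library and the median protein-coding gene 331 to 1542, so small changes of XUTs were measured with less precision. The 2 replicates of each group differed by more than sampling noise, with a chi-square per feature of 4.06 in WT with DMSO, 4.40 in WT with CHX, 17.3 in upf1 with DMSO and 12.7 in upf1 with CHX. No pair was counted as a single library.

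Densities were analysed as log2(density + 0.005488), where the pseudocount is the 5th percentile of the values above 0, so log2 fold changes understate the change of low features. Features with a mean density below the pseudocount were left out (293), and 11700 were tested. All 8 libraries entered 1 linear model in limma 3.58.1 (R 4.3.3), with a mean per group, 4 residual degrees of freedom and an empirical Bayes moderated test with a mean-variance trend. The 5 comparisons were CHX in WT, CHX in upf1, upf1 against WT in DMSO, upf1 against WT in CHX, and the difference of the CHX effects. Adjusted p-values are Benjamini-Hochberg values over all features tested in a comparison, and the threshold was 0.05. Features are called higher or lower when they passed it. Standard errors (SE) come from the model, and every adjusted p of a single gene is limma's.

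Because the deposited scale shifts the median mRNA between groups, each comparison was also fitted after rescaling the libraries by the median of ratios over 5817 protein-coding genes. Those values are called mRNA-rescaled, and log2 values called relative to the mRNA median are a median minus the median over tested protein-coding genes in the same comparison.

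Transcript classes and gene lists of at least 5 tested members were tested with camera (limma), which asks whether a set moves against the other features (against the other protein-coding genes for lists), with a preset correlation of 0.01 between genes and adjustment over sets and comparisons. Camera compares moderated t-statistics, which divide a change by its standard error, and not the changes themselves. Where nearly all features rise, a set measured less precisely can therefore point down although its median change is larger. The estimated correlation within each set and fry, a rotation test of whether a set moves at all, were alternatives. The 23 gene lists were fixed before the data were examined, as were the groups, the tests and the alternatives, except those named as added. They held the ribosomal proteins, ribosome biogenesis, the environmental stress response, Hsf1 chaperone targets, Gcn4 targets, glycolysis and fermentation, nitrogen catabolite repression, histones, G1/S genes, G2/M and M/G1 genes, the iron regulon, the phosphate regulon, the pleiotropic drug response, mRNAs reported as targets of nonsense-mediated decay (NMD), NMD and cytoplasmic decay factors, translation factors, nuclear respiration genes, mitochondrially encoded genes, intron-containing genes outside the ribosomal proteins, alpha-cell genes, a-cell genes, meiosis genes and strain label checks. Counts adjusted over the list alone used only the p-values of a list's members.

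Genes named in the text follow a rule fixed with the lists. For CHX in WT and upf1 against WT in DMSO these were the 6 protein-coding genes with the largest increase and the 6 with the largest decrease, and the 4 XUTs with the largest increase, past the threshold, with both replicates of a group above both of the other and a mean in the higher group at or above the median mean of tested protein-coding genes or XUTs. For the other comparisons they were 3 genes in each direction and 2 XUTs. The condition on replicates was not used for the difference of the CHX effects, which compares 4 groups. Of each list, the 3 members with the smallest adjusted p for CHX in WT and the 2 for upf1 against WT in DMSO could be named. NAM7, the gene that encodes Upf1, came first, with HIS3, LEU2, MET17 and URA3 as checks of the strain. Of these 5, 4 were matched and 2 tested, NAM7 and HIS3, since LEU2 and URA3 lay below the filter and MET17 was not analysed here. Dubious genes and genes overlapping another on the same strand were passed over. Genes outside the rule are named with the statement that they were chosen after their values were seen.

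The test was tried on simulated data with 200 changed features per comparison, drawn from the recovered reads' means and library sizes with a dispersion of 0.00407. As many features were raised as lowered, 1 dispersion served all groups, and no library was shifted as a whole. In the data most features moved the same way after CHX, and replicates of upf1 differed more than those of WT. The rates that follow need not carry over to such data. For CHX in WT (11170 features) 67.0% of the features changed 2-fold and 84.0% of those changed 4-fold were found, with 7.69% false calls. The corresponding shares were 61.1%, 85.7% and 1.39% for upf1 against WT in DMSO (11162 features). For CHX in upf1 they were 59.4%, 90.5% and 2.05%, for upf1 against WT in CHX 57.3%, 91.6% and 7.79%, and for the difference of the CHX effects 44.8%, 75.8% and 0%, over 11162 features each.

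Comparisons that share libraries were set beside 20 simulations of unchanged groups against the same control libraries. Random lists matched on mean density were drawn 10000 times. Intervals for features with 3 reads or fewer in a group are exact 95% Clopper-Pearson intervals of pooled reads and cover counting error only. Ordinary alternatives were other pseudocounts, filters and thresholds, no mean-variance trend, only the 4 libraries compared, rescaling on snoRNAs or mRNAs, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were voom weights (limma) on the recovered reads, set tests with an estimated correlation on mRNA-rescaled libraries, and intron-containing genes restricted to introns of at least 50 nt. Planned count models on reads were not run, since the deposited values are densities, nor was rescaling on external standards. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, intervals and plots.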

Results

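The series addressed how cytoplasmic non-coding transcripts of budding yeast are degraded, and whether their decay depends on translation and on Upf1, the RNA helicase at the centre of nonsense-mediated decay (NMD). Total RNA was sequenced from WT and upf1 cells treated with CHX or with DMSO alone, with 2 replicates in each of the 4 groups. The libraries held 10.44 M and 21.05 M reads (M for 1e+06) in WT with DMSO, 12.17 M and 13.98 M in WT with CHX, 22.09 M and 16.31 M in upf1 with DMSO, and 25.66 M and 9.09 M in upf1 with CHX. Protein-coding genes took 83.0% to 89.5% of the reads of each library. The non-coding transcripts are XUTs (degraded by the cytoplasmic exonuclease Xrn1), SUTs (stable unannotated transcripts), CUTs (cryptic unstable transcripts, degraded by the nuclear exosome) and NUTs (seen when the termination factor Nrd1 is depleted).

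NAM7, the gene of Upf1 (YMR080C, build R64, chromosome XIII, 426712 to 429627), separated the genotypes in every library. Its 1901 and 3868 reads in WT with DMSO and 3300 and 4143 in WT with CHX stood against 134 and 96 in upf1 with DMSO and 161 and 45 in upf1 with CHX. The density was 0.561 ± 0.0382 (SD, n = 2) in WT with DMSO and 0.0228 ± 0.00168 (SD, n = 2) in upf1 with DMSO, a log2 change of -4.32 (SE 0.16, limma adjusted p = 2.66e-07). With CHX the densities were 1.61 ± 0.185 in WT and 0.0362 ± 0.00165 in upf1 (SD, n = 2 each), a log2 change of -5.27 (adjusted p = 4.43e-08). LEU2 and URA3, which the strain lacks, had 0 to 2 reads and 0 or 1 read per library. HIS3, of which the strain keeps a part, had 296 to 1570 reads, and its log2 change in upf1 with DMSO was 0.91 (adjusted p = 0.00337, mRNA-rescaled 0.22). The a-cell pheromone receptor gene STE2 had a density of 3.34 in WT with DMSO and STE3, the receptor gene of the other mating type, 0.0118.

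Against the snoRNAs, nearly all RNA polymerase II transcripts were higher after CHX, and the medians of XUTs and SUTs rose more than that of mRNAs in WT with CHX and in upf1 with DMSO. The median log2 shift from WT with DMSO was 1.55 ± 0.0656 for protein-coding genes, 2.04 for XUTs and 1.97 for SUTs in WT with CHX (SD, n = 2). In upf1 with DMSO the shifts were 0.57 ± 0.134 for protein-coding genes, 1.33 for XUTs and 1.43 for SUTs, and in upf1 with CHX they were 1.88 ± 0.207, 2.39 and 2.39. XUTs thus exceeded mRNAs by 0.49 ± 0.082, 0.76 ± 0.0511 and 0.52 ± 0.0474 in the 3 groups, each gap larger than the spread between replicates. CUTs and NUTs shifted by 1.72 and 1.87 in WT with CHX but by 0.42 and 0.71 in upf1 with DMSO. CUTs lay 0.17 above mRNAs in WT with CHX and -0.16 relative to them in upf1 with DMSO. tRNAs shifted by 0.99 in WT with CHX and -0.36 in upf1 with DMSO, and mitochondrial mRNAs by 0.22 and 0.31. The snoRNAs, on which the libraries were scaled, shifted by 0.02 and 0.01, and the snRNAs of the spliceosome by 0.08 and -0.02. The median XUT density was 0.0113 in WT with DMSO, 0.0665 in WT with CHX, 0.0368 in upf1 with DMSO and 0.0836 in upf1 with CHX. That of protein-coding genes was 0.209, 0.674, 0.364 and 0.885 in the same order.

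**Figure D1:**
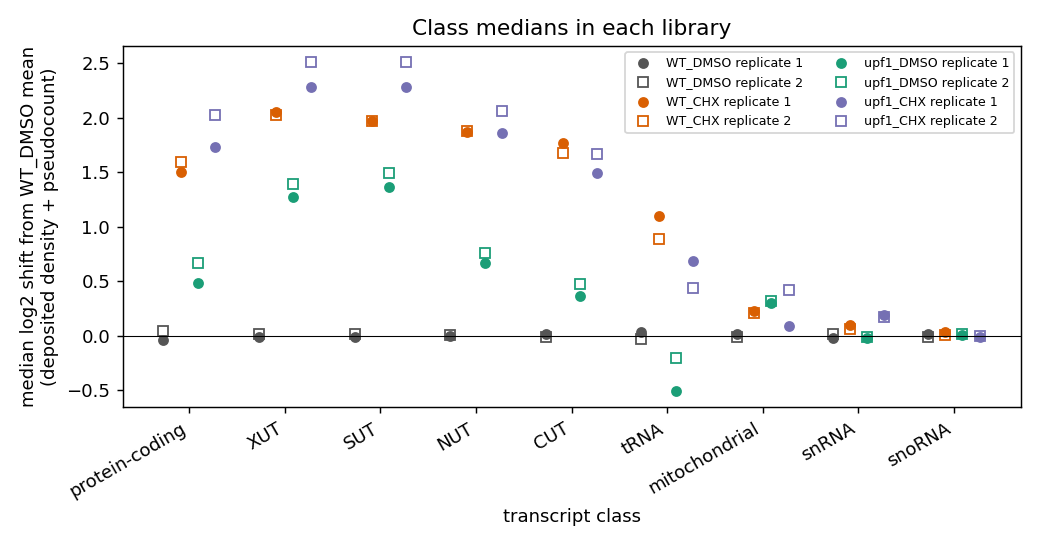
Median log2 shift of each transcript class from its mean in WT with DMSO (vertical axis, deposited density plus pseudocount), with 1 point per library, filled for replicate 1 and open for replicate 2. XUTs and SUTs lie above protein-coding genes in every library with CHX or without Upf1, while snoRNAs and snRNAs stay near 0.

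The comparison of CHX with DMSO in WT asks which RNAs accumulate within 15 min of blocking translation elongation. CIT2, the peroxisomal citrate synthase of the retrograde response (YCR005C, chromosome III, 120946 to 122328), rose from a density of 0.352 ± 0.101 to 28.5 ± 3.61 (SD, n = 2 each), a log2 change of 6.34 (SE 0.20, limma adjusted p = 1.32e-08). NRG1, a repressor of glucose-repressed genes (chromosome IV, 542674 to 543369), rose from 0.0849 to 3.93, a log2 change of 5.45 (SE 0.15), and both lay far above the mRNA median of 1.55. The XUTs rose with them, 1573 of 1611, and by 2-fold or more 93.5% of XUTs did so (1506) against 80.8% of protein-coding genes (4767 of 5897). This difference in shares had an adjusted p of 6.32e-39 by Fisher's exact test, two-sided, across features that are not independent replicates, whereas the shares past the threshold alone, 97.6% and 97.7%, were not shown to differ (adjusted p = 0.974).

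In all, 11112 features were higher and 9 lower after CHX in WT (limma), and 5156 and 2216 on mRNA-rescaled libraries. Among protein-coding genes 5762 were higher and 0 lower by limma, with 0 lower at an unadjusted p under 0.05 and 0 by voom, and after mRNA rescaling 2059 were higher and 1811 lower. XUTs were 1573 higher and 0 lower (0 at an unadjusted p, 0 by voom), and 1020 and 33 after mRNA rescaling. SUTs were 789 higher of 820 (rescaled 496 higher and 29 lower), NUTs 1433 of 1485 (955 and 77) and CUTs 845 of 916 (365 and 61). Of 283 tRNAs 162 were higher and 4 lower, but 5 and 74 after rescaling on mRNAs. After mRNA rescaling, where the fixed pseudocount also weighs less on low features in WT with DMSO, the class test of XUTs against all other features gave an adjusted p of 2.30e-08 (camera). On the deposited scale it gave 0.148, and 0.800 with an estimated correlation. It passed the threshold without replicate 1 or 2 of WT with DMSO (adjusted p = 0.00709 and 0.0267) or replicate 2 of WT with CHX (0.0136). For CUTs that test, which compares t-statistics and not changes, pointed down (camera adjusted p = 4.32e-04) although their median of 1.70 lay above that of mRNAs. It was lost with an estimated correlation (adjusted p = 0.389) and after mRNA rescaling (0.2515, and 0.774 with both, pointing up).

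By the rule for named genes, which asks for separate replicates and a density at or above the median, the other protein-coding genes with the largest increases were SPO24 (log2 5.22, mRNA-rescaled 3.68), DPI8 (4.97, 3.46), YHR022C (4.88, 3.46) and YER053C-A (4.67, 3.20), and CIT2 and NRG1 kept rescaled values of 4.82 and 3.95. Among XUTs, XUT0977 had the largest increase, a log2 change of 5.74 (SE 0.24, adjusted p = 6.06e-08) from 2 and 9 reads to 165 and 159. XUT0333 rose by 4.64 from 7 and 25 reads to 209 and 268, and XUT0190 by 4.57 from 3 and 8 to 74 and 72. XUT0495 had 1 read over both WT libraries with DMSO and 29 over both with CHX, a density ratio of 63.7 with a counting interval of 10.6 to 2601, and its fitted log2 change of 4.72 depends on the pseudocount.

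Lists of growth and energy genes had medians below that of mRNAs, and none of their tests held with an estimated correlation (adjusted p = 0.9997 each). With that choice every list in this comparison had the same adjusted p, so a call lost with it is no evidence against a list. Of 138 ribosomal protein genes 137 were higher, but their median of 0.82 lay -0.73 relative to the mRNA median (camera adjusted p = 4.69e-08, down), and after mRNA rescaling 4 were higher and 127 lower. This median lay inside the range of random lists matched on density (0.61 to 0.83), as did that of the translation factors (0.73 to 1.01). RPL22B (log2 2.67) and RPS9A (2.55), both minor paralogs, went beyond the median of mRNAs. Of 34 translation factor genes, all higher, the median was 0.94, or -0.61 relative to mRNAs (adjusted p = 2.05e-04), with GCD2 of eIF2B at 1.68 (rescaled 0.16) and 28 lower after rescaling. The 42 nuclear respiration genes, all higher, had a median of 0.83 (-0.72 relative, adjusted p = 1.02e-06, rescaled 38 lower), with the citrate synthase gene CIT1 at 1.61 (rescaled 0.08). Of 17 genes of glycolysis and fermentation 7 were higher (6 adjusted over the list alone) and 10 not past the threshold, with a median of 0.28 (-1.27 relative, adjusted p = 1.04e-09). TDH1, a minor glyceraldehyde-3-phosphate dehydrogenase gene, was at 1.54 (rescaled 0.01), and after rescaling 15 of the 17 were lower. Of 25 Hsf1 chaperone targets 19 were higher and 6 not past the threshold, with a median of 0.50 (-1.05 relative, adjusted p = 1.04e-09, rescaled 3 higher and 22 lower), although the stress chaperone genes HSP26 (2.21) and SSA4 (2.04) rose more. Of 8 mitochondrially encoded genes 2 were higher, ATP6 (0.45, adjusted p = 0.00930) and COB (0.46, adjusted p = 0.0145), both of which turned negative after rescaling (-1.09 and -1.05). Both calls were lost when adjusted over the list alone and on leaving out single libraries, at 0.40 and 0.38 for ATP6 without replicate 1 of WT with DMSO or with CHX. For COB this held at 0.42 without replicate 2 of WT with DMSO and at 0.49 and 0.43 without replicates 1 and 2 of WT with CHX. The median of the 8 was 0.21 (-1.34 relative, adjusted p = 1.45e-08, rescaled 8 lower).

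Amino acid and cell cycle lists lay on both sides of the mRNA median, with no test held under an estimated correlation (adjusted p = 0.9997 each). Of 37 Gcn4 targets 36 were higher, with a median of 1.17 (-0.38 relative, adjusted p = 0.170, and 0.00846 after mRNA rescaling, with 7 higher and 22 lower) and the serine biosynthesis gene SER3 at 2.78. All 31 G1/S genes were higher, with a median of 1.17 (-0.38 relative, adjusted p = 0.0409, rescaled 3 higher and 17 lower) and the cyclin gene PCL1 at 2.57. All 30 G2/M and M/G1 genes were higher, with a median of 1.86 (0.31 relative, adjusted p = 0.00306, up, rescaled 18 and 5), including the daughter-specific cell wall genes SCW11 (2.40) and EGT2 (2.16). All 10 histone genes rose, with a median of 1.91 (0.36 relative, adjusted p = 0.00458, rescaled 7 and 2), and the H3 and H4 genes HHT1 and HHF1 were at 2.27 and 2.25. The tests of the histone and G1/S lists were lost without replicates 1 and 2 of upf1 with CHX (adjusted p = 0.0550 and 0.0536, and 0.522 and 0.530), and that of the histones also after mRNA rescaling (0.132). Of 70 ribosome biogenesis genes all were higher, with a median of 1.47 (-0.08 relative, adjusted p = 0.896, rescaled 11 and 21) and NOP53 at 1.66 (rescaled 0.14). Of 218 intron-containing genes outside the ribosomal proteins 195 were higher (194 adjusted over the list alone) and 23 not past the threshold, with a median of 1.18 (-0.37 relative, adjusted p = 3.09e-06, rescaled 46 and 103). Of 174 of these with introns of at least 50 nt, 169 were higher, with a median of -0.27 relative to mRNAs (adjusted p = 0.00871, down, rescaled 43 and 77). MUD1, a U1 snRNP protein gene of this list, was at 2.46, and PCH2, a meiotic checkpoint gene, at 3.50 from 5 and 7 reads to 92 and 112.

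Stress, nitrogen and phosphate lists had medians above that of mRNAs, but no test of these lists held with an estimated correlation (adjusted p = 0.9997 each). All 44 genes of the environmental stress response were higher, with a median of 1.93 (0.38 relative, adjusted p = 0.0631, rescaled 22 higher and 7 lower), among them the catalase gene CTT1 (2.84) and the kinase gene YAK1 (2.61). All 19 genes under nitrogen catabolite repression were higher, with a median of 1.99 (0.44 relative, adjusted p = 0.0434, rescaled 14 and 1), including PUT1 of proline use (3.29) and the urea transporter gene DUR3 (3.12), and this test was lost without replicates 1 and 2 of upf1 with CHX (adjusted p = 0.282 and 0.305). All 16 phosphate regulon genes were higher, with a median of 2.03 (0.48 relative, adjusted p = 3.80e-05, rescaled 9 and 3), including PHM8 (3.32) and SPL2 (3.11), and the set test was lost after mRNA rescaling (adjusted p = 0.0743). All 21 iron regulon genes were higher with a median of 1.61 (0.06 relative, adjusted p = 0.729, rescaled 9 and 7) and the reductase gene FRE3 at 2.69. All 16 genes of the pleiotropic drug response were higher with a median of 1.69 (0.14 relative, adjusted p = 0.571, rescaled 7 and 3) and RTA1 at 3.17.

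All 23 mRNAs reported as NMD targets were higher, with a median of 1.99 (0.44 relative, adjusted p = 4.64e-04, up, rescaled 15 higher and 4 lower). With an estimated correlation this test and those of the next lists had an adjusted p = 0.9997 each. Among them were EST2, the catalytic subunit of telomerase (3.31), DAL7 of allantoin use (3.05) and CPA1, whose leader holds a regulatory upstream reading frame (2.33). All 28 NMD and cytoplasmic decay factor genes were higher with a median of 1.36 (-0.19 relative, adjusted p = 0.695, rescaled 6 and 12), with UPF3 at 2.23 and the decapping enzyme gene DCP2 at 1.88. All 20 meiosis genes were higher with a median of 2.15 (0.60 relative, adjusted p = 0.500, rescaled 15 higher, and adjusted p = 1.33e-04 after mRNA rescaling), including IME2 (3.56) and SPS4 (3.06). All 7 a-cell genes were higher with a median of 1.60 (0.05 relative, adjusted p = 0.223, rescaled 2 and 1), STE2 at 2.02. All 4 alpha-cell genes, too few for a set test, were higher with a median of 2.10, STE3 at 3.28. NAM7 itself rose by 1.51 in WT (adjusted p = 4.48e-06), close to the mRNA median, with -0.02 after rescaling, and HIS3 was at 1.74 (0.21).

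Counts adjusted over the list alone equalled those over all features except where given. The 9 lower features were 20 without replicate 1, and also without replicate 2, of WT with CHX.

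The comparison of upf1 with WT in DMSO asks which RNAs depend on Upf1 in growing cells. SLO1, a small gene tied to vesicle traffic (YER180C-A, chromosome V, 550865 to 551122), rose from a density of 0.0773 to 1.43, a log2 change of 4.13 (SE 0.17, limma adjusted p = 2.66e-07). DAL7, the malate synthase of allantoin use (YIR031C, chromosome IX, 413015 to 414679), rose by 4.03 and is one of the mRNAs reported as NMD targets, 21 of 23 of which were higher, with a median of 1.56. XUTs were higher in 1281 of 1611 cases (79.5%) against 66.7% of protein-coding genes, and 63.5% of XUTs (1023) and 22.1% of protein-coding genes (1302) rose 2-fold or more. Both differences passed Fisher's exact test, two-sided, across features that are not independent replicates (adjusted p = 9.89e-24 and 3.89e-207).

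The mRNA median rose by 0.57, and 7251 features were higher and 104 lower in upf1, against 3642 and 2427 on mRNA-rescaled libraries. Protein-coding genes were 3934 higher and 24 lower (rescaled 1376 and 1854), XUTs 1281 and 1 (942 and 36), SUTs 650 and 1 (516 and 29), NUTs 836 and 1 (521 and 91) and CUTs 304 and 12 (145 and 128). The share of CUTs that were higher, 33.2%, was below that of protein-coding genes (Fisher's exact test, two-sided, adjusted p = 6.41e-81), with 18.1% against 22.1% at 2-fold or more (adjusted p = 0.0102). After mRNA rescaling 15.8% of CUTs were higher against 23.3% of protein-coding genes (adjusted p = 3.35e-07) and 14.0% lower against 31.4% (6.27e-30). Of 283 tRNAs 5 were higher and 59 lower (rescaled 2 and 145). The class test of XUTs gave an adjusted p of 8.58e-08 (camera, up), and 0.356 with an estimated correlation.

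Next to SLO1 on the same strand, the meiotic gene ISC10 rose by 3.65. PAU7, whose reads can be shared with its multigene family, was at 3.61, the SWR1 complex gene SWC7 at 3.49 and YNR068C at 3.48. After NAM7, the largest decreases by the rule for named genes were those of the iron uptake oxidase gene FET3 (chromosome XIII, 388822 to 390732), with a log2 change of -0.75 (adjusted p = 0.00130, rescaled -1.45), SPL2 (-0.72), the cell wall protein genes TIP1 (-0.67) and CWP1 (-0.65), and the acid phosphatase gene PHO12 (-0.60), which has a near-identical copy in PHO11. Genes passed over by that rule include larger decreases, such as that of PHO89 (-1.72). Without replicate 2 of WT with DMSO or replicate 1 of upf1 with DMSO the calls of SPL2 (-0.55 and -0.44), TIP1 (-0.52 and -0.40) and PHO12 (-0.32 and -0.47) were lost, and that of PHO12 also without replicate 2 of upf1 with DMSO (-0.72). Among XUTs, XUT1467 (3.99) and XUT1612 (3.53) had large increases. XUT0788 had 1 read over both WT libraries and 166 over both upf1 libraries, a density ratio of 164.8 with a counting interval of 29.2 to 6548, and XUT0495 had 1 and 29, a ratio of 28.8 with an interval of 4.77 to 1176. Their fitted log2 changes, 4.37 and 3.68, depend on the pseudocount.

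**Figure D2:**
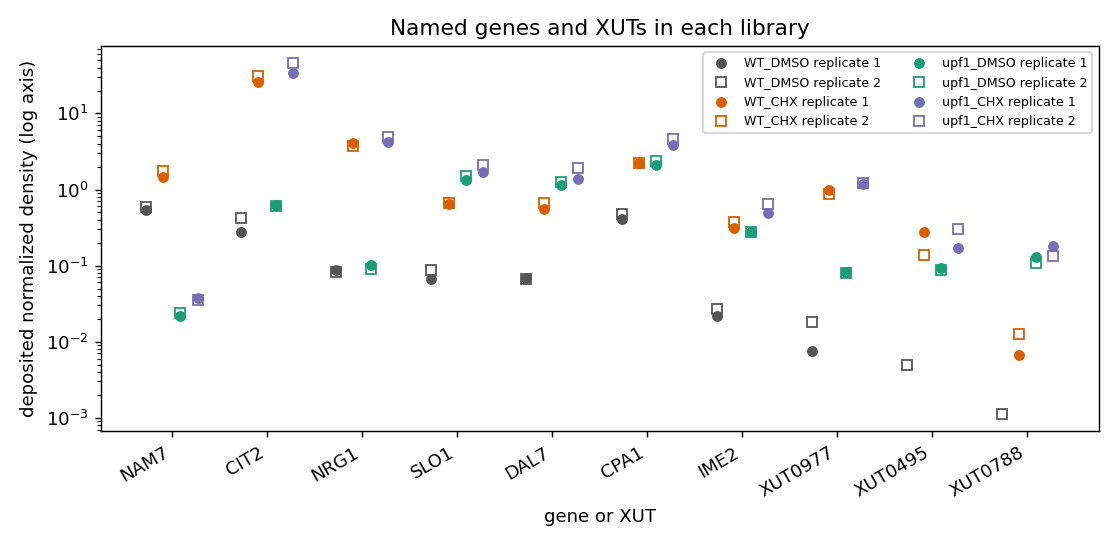
Deposited density (vertical axis, log scale) of NAM7 and of named genes and XUTs in each library, filled for replicate 1 and open for replicate 2. Values of 0, those of XUT0495 and XUT0788 in replicate 1 of WT with DMSO, are not drawn.

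The NMD target list stood 1.00 above the mRNA median (camera adjusted p = 2.85e-11), with 18 higher and 3 lower after rescaling. It lost this call with an estimated correlation, as did the meiosis and nitrogen lists (adjusted p = 0.9997 each). STN1 of telomere capping, an NMD target of the list, was at 3.36. Outside the NMD target list, NBL1 was at 2.96 and MAY24 at 2.67. NMD4, a partner of Upf1 from the decay factor list, was at 2.49. Of 20 meiosis genes 15 were higher, with a median of 1.5 (0.93 relative, adjusted p = 0.00549, rescaled 12 higher), including IME2 (3.25) and ZIP1 (2.56). Of 19 genes under nitrogen catabolite repression 14 were higher (15 adjusted over the list alone), with a median of 0.70 (0.13 relative, adjusted p = 0.0357, rescaled 7 and 1), including the allantoin genes DAL5 (3.48) and DAL2 (3.10). Of 28 decay factor genes 18 were higher and 1 lower (19 and 1 adjusted over the list alone), and the lower one was NAM7, the mutated gene itself. Their median was 0.42 (-0.15 relative, camera adjusted p = 0.102, rescaled 4 and 14). The tests of the nitrogen and meiosis lists were also lost without replicates 1 and 2 of upf1 with CHX (0.292 and 0.307, 0.109 and 0.118), and that of the nitrogen list without replicate 1 of upf1 with DMSO (0.0597).

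Stress and amino acid genes as groups had medians near that of mRNAs while single members rose further. Of 44 stress response genes 25 were higher, 2 lower and 17 not past the threshold (median 0.57, 0.00 relative, adjusted p = 0.684, rescaled 15 and 15), and the peroxidase gene GPX1 (2.77) and RTN2 (2.51) were the leading members. Of 25 Hsf1 targets 21 were higher (median 0.64, 0.07 relative, adjusted p = 0.896, rescaled 4 and 8), with the chaperone genes SSA3 and SSA4 at 2.24 and 1.60. Of 37 Gcn4 targets 26 were higher (27 adjusted over the list alone), with ARG8 at 2.14 and SER3 at 1.99. Their median of 0.48 lay -0.09 relative to mRNAs while the test pointed up (adjusted p = 0.931, rescaled 8 and 14). Of 70 ribosome biogenesis genes 45 were higher (46 adjusted over the list alone), with a median of 0.55 (-0.02 relative, adjusted p = 0.162, rescaled 2 and 20) and NOC4 at 1.07. Of 218 intron-containing genes 152 were higher (156 adjusted over the list alone), with a median of 0.59 (0.02 relative, adjusted p = 0.970, rescaled 58 and 54), and with introns of at least 50 nt 126 of 174 were (131 adjusted over the list alone, median 0.05 relative, adjusted p = 0.920, rescaled 47 and 54).

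Ribosomal protein, energy, histone and phosphate lists lay below the mRNA median by camera, and none of these calls held with an estimated correlation (adjusted p = 0.9997 each). Of 138 ribosomal protein genes 19 were higher (6 adjusted over the list alone) and 119 not past the threshold, with a median of 0.20 (-0.36 relative, adjusted p = 6.01e-08, rescaled 1 higher and 130 lower). RPL22B (1.85) and RPL28 (0.84, rescaled 0.14), which hold introns, led them. Of 17 glycolysis genes 2 were higher, 1 lower and 14 not past the threshold (median 0.01, -0.55 relative, adjusted p = 4.21e-05, rescaled 16 lower), with the decarboxylase gene PDC5 at 0.90 (rescaled 0.24) and TDH1 at -0.61. Of 34 translation factor genes 18 were higher (11 adjusted over the list alone, median 0.38, -0.19 relative, adjusted p = 0.0326, rescaled 26 lower), and of 42 respiration genes 15 (10 adjusted over the list alone, median 0.23, -0.33 relative, adjusted p = 2.30e-04, rescaled 31 lower). The translation factor test was lost without replicate 2 of WT with DMSO (0.0679), replicate 1 of upf1 with DMSO (0.0554), and replicates 1 and 2 of upf1 with CHX (0.0590 and 0.0593). Of 10 histone genes 1 was higher, HHT2 at 0.40, a call lost when adjusted over the list alone (median 0.09, -0.48 relative, adjusted p = 0.0128, rescaled 10 lower). Of 16 phosphate regulon genes 3 were higher and 5 lower (3 and 3 adjusted over the list alone, rescaled 2 and 13), from GIT1 at 2.96 to the phosphate transporter gene PHO89 at -1.72. Their median was -0.12 and their mean 0.02 (-0.69 relative, adjusted p = 3.27e-05, down). Of 8 mitochondrially encoded genes 2 were higher, calls lost when adjusted over the list alone (median 0.20, -0.37 relative, adjusted p = 0.0144, rescaled 7 lower).

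Of 21 iron regulon genes 10 were higher, 5 lower and 6 not past the threshold (median 0.41, -0.16 relative, adjusted p = 0.260, rescaled 7 and 9), with the reductase genes FRE2 and FRE3 at 2.76 and 2.63. Of 31 G1/S genes 23 were higher (24 adjusted over the list alone, median 0.47, -0.10 relative, adjusted p = 0.105, rescaled 2 and 11), with CSI2 at 0.96, and of 30 G2/M and M/G1 genes 20 (median 0.46, -0.11 relative, adjusted p = 0.243, rescaled 1 and 15), with DSE3 at 1.45. Of 16 drug response genes 8 were higher (median 0.46, -0.10 relative, adjusted p = 0.896, rescaled 3 and 5), with the transporter gene FLR1 at 2.94. Of 7 a-cell genes 0 were higher and 0 lower by limma, with 0 higher and 1 lower both at an unadjusted p under 0.05 and by voom (median -0.11, -0.68 relative, adjusted p = 8.49e-04, down, rescaled 7 lower), a set test lost with an estimated correlation (adjusted p = 0.9997). STE2 was at 0.24 (adjusted p = 0.132). Of 4 alpha-cell genes 2 were higher, SAG1 at 2.52 and STE3 at 1.70 (median 1.05).

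**Figure D3:**
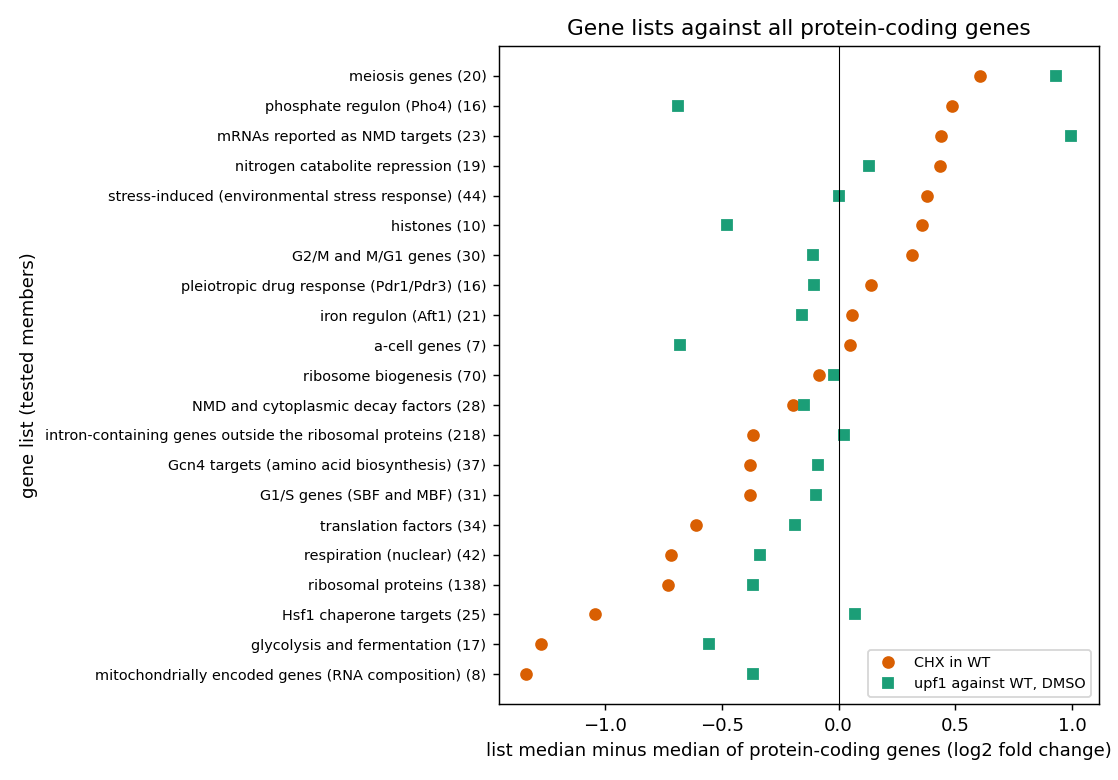
Median log2 change of each gene list minus the median of all tested protein-coding genes (horizontal axis), for CHX in WT (circles) and for upf1 against WT in DMSO (squares), with the number of tested members. NMD targets and meiosis genes lie above 0 in both comparisons, while ribosomal protein, glycolysis and respiration genes lie below 0 in both.

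The comparison of CHX with DMSO in upf1 asks what a translation block adds when Upf1 is missing. CIT2 and NRG1 led again, with log2 changes of 5.98 and 5.49 (SE 0.20 and 0.15, limma adjusted p = 3.32e-08 and 9.94e-09), followed by YER053C-A at 4.64. XUTs, by contrast, had a median of 0.98, below the mRNA median of 1.14 (mRNA-rescaled -0.11 and -0.05). Among XUTs 85.7% (1380) were higher, against 95.5% of protein-coding genes (Fisher's exact test, two-sided, across features that are not independent replicates, adjusted p = 1.52e-37). After mRNA rescaling XUTs passed the threshold less often in both directions, 7.14% against 22.1% higher and 13.35% against 28.8% lower. XUTs had fewer reads, so such shares do not by themselves show a smaller rise. XUT0977 still rose by 3.80, and XUT1381 had 3 reads in upf1 with DMSO and 45 with CHX, a density ratio of 27.4 with a counting interval of 8.79 to 137.8.

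In upf1, 10416 features were higher and 27 lower after CHX, but 1880 and 2499 after mRNA rescaling. Protein-coding genes were 5632 and 3 (rescaled 1303 and 1696), XUTs 1380 and 2 (115 and 215), SUTs 694 and 3 (50 and 191), CUTs 729 and 2 (90 and 80) and NUTs 1327 and 3 (197 and 147). The class test of XUTs pointed down (camera adjusted p = 2.13e-04), and was lost after mRNA rescaling (adjusted p = 0.626) and with an estimated correlation (0.498). Of the gene lists no test in this comparison held with an estimated correlation (adjusted p = 0.9997 each). All 44 stress response genes were higher, with a median of 1.64 (0.50 relative to mRNAs, adjusted p = 5.70e-09, rescaled 21 higher and 1 lower). The 16 phosphate genes (median 1.65, 0.51 relative, adjusted p = 2.28e-08, rescaled 10 higher), the 30 G2/M and M/G1 genes (1.69, 0.55 relative, adjusted p = 5.14e-07, rescaled 18 and 2) and the 10 histone genes (1.62, 0.48 relative, adjusted p = 7.64e-04, rescaled 7 and 2) were all higher, with medians above that of mRNAs. The 7 a-cell genes had a median 0.43 above that of mRNAs (adjusted p = 0.00871, rescaled 3 and 1), a set test lost after mRNA rescaling (adjusted p = 0.0540). Ribosomal protein genes (137 of 138 higher, -0.41 relative, adjusted p = 0.00228, rescaled 7 and 123), Hsf1 targets (17 of 25, -0.69 relative, adjusted p = 1.56e-06, rescaled 1 and 20) and glycolysis genes (7 of 17, or 6 adjusted over the list alone, -0.85 relative, adjusted p = 9.75e-06, rescaled 1 and 15) lay below the mRNA median. All 23 NMD targets were higher, yet -0.22 relative to mRNAs (adjusted p = 0.500, rescaled 5 and 11). All 20 meiosis genes were higher with a median 0.15 above mRNAs while the test pointed down (adjusted p = 0.0475), a call lost after mRNA rescaling (0.280). Of the alpha-cell genes 3 of 4 were higher. NAM7 was at 0.56 (adjusted p = 0.00713, rescaled -0.44) and HIS3 at 1.2 (rescaled -0.01). The 27 lower features were 16 without replicate 2 of upf1 with DMSO and 72 without replicate 1 of upf1 with CHX.

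The comparison of upf1 with WT under CHX asks whether loss of Upf1 still matters once translation is blocked. COS12, a subtelomeric gene of a multigene family whose reads can be shared (chromosome VII, 2790 to 3932), had the largest increase by the rule for named genes, 3.06 (SE 0.21, limma adjusted p = 8.62e-05), followed by ULI1 at 1.92 and OTU1 at 1.80. Besides NAM7, the phosphate genes PHO89 (-1.74) and PHM6 (-1.09) had the largest decreases by that rule. Of 1611 XUTs 331 were higher (20.5%), a share not shown to differ from that of protein-coding genes (19.8%, Fisher's exact test, two-sided, adjusted p = 0.596), and XUT0788 (3.45) and XUT1657 (2.74) led them. By 2-fold or more 8.44% of XUTs and 3.07% of protein-coding genes were higher (adjusted p = 4.34e-18), and after mRNA rescaling 6.52% and 7.60% were higher without the size limit (adjusted p = 0.195). CUTs were lower in 6.55% of cases against 0.339% of protein-coding genes (adjusted p = 8.08e-36), and after mRNA rescaling in 14.1% against 11.4% (adjusted p = 0.0310).

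The mRNA median was 0.32, with 1931 features higher and 169 lower, and 686 and 1080 after mRNA rescaling. Protein-coding genes were 1165 and 20 (rescaled 448 and 671), XUTs 331 and 15 (105 and 50), SUTs 233 and 2 (90 and 22), NUTs 126 and 12 (21 and 82), CUTs 18 and 60 (6 and 129) and tRNAs 4 and 44 (2 and 66). The class test of XUTs gave an adjusted p of 0.516 (camera), 0.00748 after mRNA rescaling, 0.926 with an estimated correlation and 0.430 with both. The list calls that follow were all lost with an estimated correlation (adjusted p = 0.9997 each). Stress response genes were raised in 31 of 44 cases (36 adjusted over the list alone, 0.31 relative, adjusted p = 1.43e-06), Hsf1 targets in 15 of 25 (20 adjusted over the list alone, 0.20 relative, adjusted p = 6.10e-05) and NMD targets in 15 of 23 (18 adjusted over the list alone, 0.40 relative, adjusted p = 1.58e-06), with 8, 7 and 12 higher after rescaling. Phosphate genes were 2 higher and 3 lower (median -0.13, -0.46 relative, adjusted p = 6.86e-10, rescaled 1 and 11) and iron regulon genes 3 and 3 (4 and 5 adjusted over the list alone, median 0.02, mean -0.02, adjusted p = 2.80e-05, down, rescaled 2 and 8). The histone genes (median -0.22, adjusted p = 3.66e-06, rescaled 9 lower), the ribosome biogenesis genes (0.11, adjusted p = 3.66e-06, rescaled 22 lower) and the a-cell genes (-0.20, adjusted p = 1.37e-05, rescaled 7 lower) lay below the mRNA median. By limma 0 of the 10, 70 and 7 genes were higher or lower, with 1 lower of each at an unadjusted p under 0.05 and 0, 1 (higher) and 1 (lower) by voom. Of the ribosomal protein genes 2 were higher, calls lost when adjusted over the list alone (median 0.09, adjusted p = 9.30e-07, down, rescaled 1 and 74), and of the alpha-cell genes 1. These counts depend on single libraries, with 226 higher without replicate 2 of upf1 with CHX, 3704 without its replicate 1, and 315 and 738 without replicates 1 and 2 of WT with CHX. The lower ones were 21 without replicate 1 of WT with CHX or replicate 2 of upf1 with CHX, 71 without replicate 2 of WT with CHX and 273 without replicate 1 of upf1 with CHX. The 331 higher XUTs were 41 without replicate 2 of upf1 with CHX, and 78 and 151 without replicates 1 and 2 of WT with CHX.

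The difference of the CHX effects, upf1 minus WT, tests whether CHX acts differently without Upf1. The stress genes DDR2 (1.69, SE 0.37, limma adjusted p = 0.00762), HSP42 (0.99, adjusted p = 0.0105) and TSL1 of trehalose synthesis (0.89, adjusted p = 0.0142) responded more in upf1. SLO1 responded less, with a difference of -2.60 (adjusted p = 4.70e-04), as did XUT0495 (-3.45) and XUT0178 (-2.96). XUTs as a class had a median difference of -1.03 and SUTs of -1.06, against an mRNA median of -0.27. Of 1611 XUTs 50.2% had a smaller CHX effect in upf1, against 15.0% of protein-coding genes (Fisher's exact test, two-sided, across features that are not independent replicates, adjusted p = 3.54e-174).

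In all, 24 features had a larger and 2964 a smaller CHX effect in upf1, and 288 and 2533 after mRNA rescaling. XUTs were 0 larger (limma, with 2 at an unadjusted p under 0.05 and 1 by voom) and 809 smaller (rescaled 1 and 685), SUTs 1 and 461 (1 and 416), protein-coding genes 7 and 883 (245 and 795), CUTs 1 and 203 (6 and 125) and NUTs 0 and 483 (limma, with 3 larger at an unadjusted p and 0 by voom, rescaled 6 and 419). The class test of XUTs pointed down (camera adjusted p = 2.26e-11), and was lost with an estimated correlation (adjusted p = 0.285). So were the calls of all gene lists in this comparison (adjusted p = 0.9997 each). Of 23 NMD targets 12 had a smaller effect (13 adjusted over the list alone, rescaled 12, median -0.70, -0.43 relative, adjusted p = 4.82e-09), of 20 meiosis genes 7 (9 adjusted over the list alone, rescaled 9, median -0.81, adjusted p = 2.60e-04), of 19 nitrogen genes 6 (8 adjusted over the list alone, rescaled 2 larger and 6 smaller, median -0.49, adjusted p = 0.0601) and of 21 iron genes 8 (rescaled 4 larger and 7 smaller, median -0.33, adjusted p = 0.190). Stress response genes had a larger effect in 4 cases and a smaller one in 6 (rescaled 11 and 5, median 0.00, mean -0.03, 0.28 relative, adjusted p = 1.34e-05, up). For Hsf1 targets (1 larger, 2 smaller, rescaled 10 and 2, median -0.08, adjusted p = 0.00871), ribosomal proteins (1 smaller, rescaled 9 larger and 1 smaller, median -0.11, adjusted p = 1.56e-04), glycolysis (rescaled 3 larger, median -0.01, mean 0.01, adjusted p = 0.00181) and respiration (rescaled 1 larger, median -0.03, adjusted p = 2.05e-04) the tests pointed up, since their medians, although below 0, lay above that of mRNAs. Of the alpha-cell genes 2 of 4 had a smaller effect. NAM7 was at -0.95 (adjusted p = 0.0125), and no longer past the threshold after rescaling (-0.42, adjusted p = 0.121). The calls of the very short gene YPL152W-A (-3.44, SE 1.15, adjusted p = 0.0497) and of the multicopy metallothionein gene CUP1-2 (-2.79, SE 0.84, adjusted p = 0.0318) were lost on rescaling (adjusted p = 0.158 and 0.0808). Calls were lost without replicate 1 of WT with DMSO for HSP42 (0.88), TSL1 (0.71), NAM7 (-0.88) and CUP1-2 (-1.78). They were lost without replicate 2 of WT with CHX for HSP42 (0.90), NAM7 (-0.83) and CUP1-2 (-2.48), and without replicate 1 of that group for TSL1 (0.87) and YPL152W-A (-3.01). Without replicate 2 of upf1 with DMSO those of TSL1 (0.76), CUP1-2 (-2.15) and YPL152W-A (-3.50) were lost, and YPL152W-A lost its call without replicate 1 of that group (-3.38). Without replicates 1 and 2 of upf1 with CHX it was also lost (-3.52 and -3.37), as was CUP1-2 without replicate 1 (-2.26). The 24 features with a larger effect were 10 without replicate 1 of WT with DMSO, 43 and 39 without replicates 1 and 2 of WT with CHX and 55 without replicate 2 of upf1 with DMSO, and the 2964 were 1865 without the latter.

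**Figure D4:**
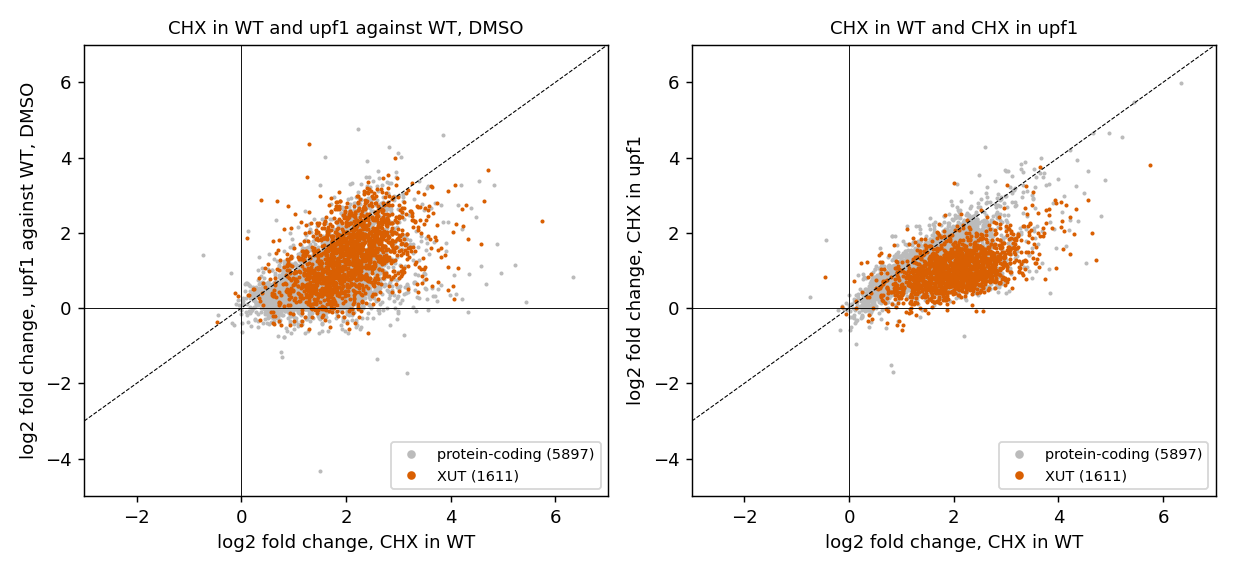
Log2 change with CHX in WT (horizontal axes) against log2 change in upf1 with DMSO (left) and with CHX in upf1 (right), with 1 point per protein-coding gene (5897, grey) or XUT (1611, orange) and the line of equal change dashed. In the right plot most XUTs lie below the line.

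The XUTs higher after CHX in WT were set beside those higher in upf1 with DMSO. Of the 1573 and 1281, 1273 were shared, where independent lists of these sizes would share 1251. With 1573 of 1611 XUTs higher after CHX this overlap is nearly fixed by the list sizes, and the 0 shared in 20 simulations of unchanged groups against the same WT libraries do not bear on it. At 2-fold or more 994 were shared of 1506 and 1023 (956.3 for independent lists), and after mRNA rescaling 779 of 1020 and 942 (596.4). Protein-coding genes shared 1268 of 4767 and 1302 at 2-fold or more (1053 for independent lists) and 926 of 2059 and 1376 after rescaling (480.4). The covariance of both log2 changes across XUTs was 0.251, against 0.0335 simulated from the shared controls, and across protein-coding genes 0.194 against 0.0181. The Pearson r across XUTs was 0.46 and across protein-coding genes 0.50. Unchanged groups set against the same controls have an r near 0.50 by construction (0.50 simulated for XUTs), so these 2 values cannot show or exclude shared effects. With no shared library, from 1 replicate per group, r was 0.37 and 0.29 across XUTs (covariance 0.232 and 0.180) and 0.46 and 0.43 across protein-coding genes (0.194 and 0.176). Part of the excess of shared XUTs over independent lists may come from the shared WT libraries. The CHX effects in WT and in upf1, which share no library, had a Pearson r of 0.53 and a Spearman rho of 0.46 across XUTs and 0.70 and 0.68 across protein-coding genes, which are not independent replicates.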

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

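The 3 tests of explanations here, of few reads, of library factors and of a shared route, were chosen only after the result was seen, whereas the difference of the CHX effects was a planned comparison. What singled out the results is that the CHX effect differed between upf1 and WT by the test of the difference itself. This held for 2964 features with a smaller effect in upf1, 809 of them XUTs, and for 24 features with a larger one. Among transcript classes the median difference, upf1 minus WT, was -1.06 for SUTs, -1.03 for XUTs, -0.72 for NUTs, -0.48 for open reading frames outside the reference annotation and -0.27 for protein-coding genes. Each of these classes lost its camera call with an estimated correlation (adjusted p = 0.2965, 0.285, 0.688, 0.392 and 0.704 in this order). For the reading frames camera pointed up (adjusted p = 0.0138) although their median lay below that of mRNAs, a call lost after mRNA rescaling (0.927). The median difference was 0.11 for snRNAs, 0.069 for rRNA features, 0.0044 for tRNAs and -0.023 for snoRNAs, classes that stood above the rest by camera (adjusted p = 0.00160, 0.00678, 1.50e-21 and 1.18e-09). With an estimated correlation their adjusted p was 0.0962 for snRNAs, 0.219 for rRNA, 0.0435 for tRNAs and 0.0243 for snoRNAs, so that the calls of snRNAs and rRNA were lost. After mRNA rescaling alone it was 0.00358, 0.217, 3.28e-10 and 8.06e-11, which lost that of rRNA, and with both choices 0.440, 0.512, 0.324 and 0.430.

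For the smaller rise of XUTs with CHX in upf1, few reads and the pseudocount as the whole cause would have to spare XUTs with at least 20 reads in both WT libraries with DMSO, but these 308 XUTs had a median difference of -1.24, which is -0.97 against the protein-coding median. The pseudocount does move the counts, since one of 0.03316 gave 397 XUTs with a smaller effect in place of 809 and 1632 features in place of 2964. Library factors would have to bring the median near 0 after rescaling on mRNAs, where it stayed at -0.93. That rescaling moved the median difference of snoRNAs only from -0.023 to 0.298 and that of mRNAs from -0.27 to 0.027. It could thus not have brought XUTs near 0, and the fixed pseudocount also enters the -0.93. The values show only that the gap between these 2 scales is too small to account for the difference. A shared route, by which CHX adds little to XUTs that loss of Upf1 has already raised, may contribute, but its test cannot decide. In separate libraries the 1003 XUTs raised at least 2-fold in upf1 had a median of -1.23. The 205 raised little had -0.47, a gap of -0.755. The difference of the CHX effects holds the upf1 effect in DMSO with a minus sign. Any loss of that effect under CHX, whatever its cause, would thus give such a gap. An upper limit on RNA levels would give the same gap, and was not tested, so that the biological explanation stays a hypothesis.

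Differences for single genes are given as values. Among XUTs they were -3.45 for XUT0495, -2.96 for XUT0178, -2.63 for XUT0333, -2.26 for XUT1612, -2.16 for XUT1467, -1.95 for XUT0977 and -1.71 for XUT0190. Nutrient, meiosis, mating and vesicle traffic genes were at -2.60 for SLO1, -2.60 for DAL7, -2.57 for IME2, -2.29 for DAL5, -2.20 for GIT1, -2.10 for ISC10, -1.88 for SPS4, -1.85 for ZIP1, -1.83 for FRE2, -1.82 for FRE3, -1.50 for DUR3, -1.49 for DAL2 and -1.32 for STE3. Of mRNAs reported as NMD targets or leading genes of the upf1 comparison, they were -2.25 for STN1, -2.14 for PAU7, -2.10 for EST2, -1.99 for YNR068C, -1.76 for SWC7 and -1.41 for CPA1. Outside both, they were -1.93 for MAY24, -1.50 for NBL1 and -1.33 for the decay factor gene NMD4. Stress, transport and amino acid genes were at -1.81 for FLR1, -1.58 for RTN2, -1.50 for SER3, -1.41 for ARG8, -1.27 for SSA3, -1.24 for GPX1, -1.08 for SSA4 and -0.69 for CTT1. The others were -3.44 for YPL152W-A, -2.79 for CUP1-2, -1.99 for ULI1, -1.49 for YHR022C, -1.19 for RPL22B, -0.96 for COS12, -0.95 for NAM7, -0.84 for NOP53, -0.77 for NOC4, -0.73 for CSI2 and -0.67 for MUD1. The calls of YPL152W-A, CUP1-2, NAM7, CTT1 and MUD1 were lost after mRNA rescaling, with differences of -3.68 (adjusted p = 0.158), -2.53 (0.0808), -0.42 (0.121), -0.46 (0.0816) and -0.37 (0.161). A larger effect in upf1 was found for DDR2 (1.69), HSP42 (0.99) and TSL1 (0.89).

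Of gene lists, the NMD targets (median difference -0.70) and meiosis genes (-0.81) stood below other protein-coding genes by camera. These calls and those that follow were lost with an estimated correlation (adjusted p = 0.9997 each, and 0.286 at the lowest with mRNA rescaling as well), but not after mRNA rescaling alone (0.0152 at the highest). The ribosomal proteins (-0.11), Hsf1 targets (-0.084), respiration genes (-0.028), glycolysis genes (-0.011) and stress response genes (0.0031) stood above them.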

How the results depend on the processing

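Voom weights, set tests with an estimated correlation on mRNA-rescaled libraries, and the restriction to introns of at least 50 nt were chosen only after the data were seen. All other alternatives were planned. A tally was kept for named genes, and for list tests past the threshold for CHX in WT, upf1 in DMSO or the difference of the CHX effects. Of its values, 2506 kept their direction and their side of the threshold, 162 lost their call, 1 gained one and 24 changed sign. List tests outside the tally could also gain a call, such as that of a-cell genes for CHX in WT with the replicate block (camera adjusted p = 0.0139). Counts of calls over all features, of XUTs higher or with a smaller CHX effect, and of shared XUTs stayed within 1.5 times under the lower pseudocount (0.001818), no filter, no mean-variance trend, rescaling on snoRNAs and voom. Counts of other classes were compared by voom alone and did not all do so. Among protein-coding genes 1929 instead of 1165 were then higher and 39 instead of 20 lower for upf1 in CHX, and 39 instead of 24 lower for upf1 in DMSO. NUTs with a smaller CHX effect were 844 instead of 483, NUTs lower for upf1 in CHX 51 instead of 12, and tRNAs lower there 27 instead of 44. Protein-coding genes with a larger CHX effect were 16 instead of 7, and those lower for CHX in upf1 7 instead of 3. For tRNAs 7 instead of 13 had a larger and 3 instead of 11 a smaller CHX effect. Other counts of 5 or fewer, and counts within gene lists, were not held to this limit.

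Rescaling on mRNAs gave 5156 higher and 2216 lower features for CHX in WT, 1880 and 2499 for CHX in upf1, 3642 and 2427 for upf1 in DMSO, 686 and 1080 for upf1 in CHX, and 288 with a larger CHX effect in upf1. XUTs higher were then 1020 for CHX in WT, 115 for CHX in upf1 and 105 for upf1 in CHX, and 779 were shared. It turned the sign of ATP6 (-1.09), COB (-1.05) and NAM7 (-0.023) for CHX in WT, and of NAM7 (-0.44) and HIS3 (-0.015) for CHX in upf1, because the median mRNA rises on the deposited scale. Single calls it ended were NOP53 (0.14), TDH1 (0.013), GCD2 (0.16), CIT1 (0.077) and HIS3 (0.21) for CHX in WT, RPL28 (0.14), PDC5 (0.24) and HIS3 (0.22) for upf1 in DMSO, and those of the difference named elsewhere. List tests that it brought past the threshold include, for upf1 in DMSO, ribosome biogenesis (adjusted p = 0.0177) and G1/S genes (0.0212), and for the difference of the CHX effects the nitrogen list (0.0463). A 2-fold minimum left 4 lower for CHX in WT, 6542 and 7 for CHX in upf1, 3707 and 41 for upf1 in DMSO, 431 and 70 for upf1 in CHX, and 775 and 136 XUTs higher for CHX in upf1 and upf1 in CHX. An adjusted p below 0.01 left 5 lower for CHX in WT, 11 lower for CHX in upf1, 53 lower for upf1 in DMSO, 444 and 16 for upf1 in CHX with 92 XUTs higher, and 6 larger and 1510 smaller CHX effects with 442 XUTs smaller, each by a stricter rule. A filter at 0.03792 (8995 features) gave 5 lower for CHX in WT. Only the 4 libraries compared gave 46 lower for CHX in upf1. A pseudocount of 0.03316 gave 325 lower for upf1 in CHX, and 1632 smaller CHX effects with 397 XUTs among them. For the filter, the 4 libraries and the pseudocount the cause was not tested.

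The replicate number as a block gave 3441 higher and 263 lower for upf1 in CHX and 42 larger CHX effects. With this block the class test of XUTs pointed down for CHX in WT (adjusted p = 0.556) and for upf1 in CHX (0.761), past the threshold in neither. List tests lost with the block were, for CHX in WT, ribosomal proteins (0.156), nitrogen (0.1155), G1/S (0.0781) and translation factors (0.0508). For upf1 in DMSO they were nitrogen (0.0576), translation factors (0.156) and meiosis (0.107), and for CHX in upf1 ribosomal proteins (0.596), translation factors (0.197) and respiration (0.1996). Class tests lost with the block were those of pseudogenes for upf1 in DMSO (0.0642), SUTs for upf1 in CHX (0.08835) and NUTs for the difference of the CHX effects (0.172). The call of YPL152W-A was lost as well (0.0590). Deviations of same-numbered libraries, each centred on its median, had correlations of -0.024 to 0.076. The centring removes a shift of a whole library, so these correlations cannot show whether the numbers pair the libraries. In every group the median shift of protein-coding genes was higher in replicate 2. It was 1.502 and 1.595 in replicates 1 and 2 of WT with CHX, and 1.729 and 2.022 in upf1 with CHX. The cause was not tested.

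The class test of XUTs had, for CHX in WT, an adjusted p of 1.28e-04 with fry, 2.30e-08 after mRNA rescaling, 0.800 with an estimated correlation and 0.226 with both. For CHX in upf1 it was 0.498 with an estimated correlation, 0.626 after mRNA rescaling, 0.854 with both, and 8.25e-04 with fry, which pointed up. For upf1 in DMSO it was 0.356 with an estimated correlation and 0.145 with both, and for the difference of the CHX effects 0.285 and 0.145. For upf1 in CHX it was 0.0224 with fry, 0.00748 after rescaling, 0.926 with an estimated correlation and 0.430 with both. Fry tests whether a set moves at all, so a list that rises less than other genes changes sign by construction. Its adjusted p-values with the opposite sign were, for CHX in WT, 0.00492 for ribosomal proteins, 0.00977 for Hsf1 targets, 0.0695 for glycolysis, 0.00224 for G1/S genes, 0.00837 for translation factors, 0.00289 for respiration, 0.311 for mitochondrial genes and 0.00228 for intron-containing genes. For upf1 in DMSO they were 0.212 for ribosomal proteins, 0.889 for glycolysis, 0.379 for histones, 0.834 for phosphate genes, 0.115 for translation factors, 0.101 for respiration and 0.591 for mitochondrial genes. For the difference of the CHX effects they were 0.591 for ribosomal proteins, 0.767 for stress genes, 0.719 for Hsf1 targets and 0.791 for respiration. On mRNA-rescaled libraries with an estimated correlation the lowest adjusted p of a list was 0.286.

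Leaving out each library in turn, where the lone library of a group is assumed to vary like the others, gave 10877 to 11147 higher and 6 to 20 lower for CHX in WT, 9254 to 10440 and 16 to 72 for CHX in upf1, 5046 to 7770 and 70 to 156 for upf1 in DMSO, and 226 to 3704 and 21 to 273 for upf1 in CHX. Larger CHX effects were 10 to 55 and smaller ones 1865 to 3758. XUTs higher were 1541 to 1577, 1117 to 1389, 1101 to 1291 and 41 to 426 in these 4 comparisons, XUTs with a smaller CHX effect 553 to 835 and shared XUTs 1095 to 1283. The adjusted p of the XUT class test was 0.00709 to 0.795 for CHX in WT, 4.54e-06 to 0.00356 for CHX in upf1, 1.84e-10 to 2.04e-05 for upf1 in DMSO, 0.0755 to 0.703 for upf1 in CHX and 7.28e-14 to 5.02e-06 for the difference. The cause was not tested.

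Depth limits the low features most, since the median XUT had 7 reads in the smaller WT library with DMSO, and changes of such XUTs depend on the pseudocount. Rescaling on external standards and count models were not run.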

Other observations

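Except for the planned test of decay coupled to translation, the tests in this part were chosen only after the result was seen, as were the features named in the next 2 paragraphs. Of 7 named non-coding RNAs, ICR1 and SRG1 were higher in both comparisons. ICR1, transcribed through the promoter of the adhesin gene FLO11, was higher by a log2 change of 2.18 after CHX in WT (limma adjusted p = 3.34e-07) and 2.74 in upf1 with DMSO (4.40e-07), with a smaller CHX effect in upf1 (-1.67). SRG1, transcribed across the promoter of SER3, was higher by 2.23 and 1.16 (difference of CHX effects -0.92), and SER3 itself by 2.78 and 1.99. The telomerase RNA TLC1 was at 0.30 (adjusted p = 0.0384) and 0.22 (0.141), the U2 snRNA LSR1 at 0.20 (0.0544) and 0.43 (0.00184), and the signal recognition particle RNA SCR1 at -0.46 (0.170) and -0.68 (0.0741). The RNAs of RNase MRP and RNase P, NME1 and RPR1, were at 0.027 (0.803) and 0.11 (0.346) and at -0.017 (0.900) and -0.067 (0.667).

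Reading frames of the 2-micron plasmid and pseudogenes were examined in the same way. The plasmid reading frames R0010W and R0040C were higher by 2.30 and 2.37 after CHX in WT and by 2.69 and 2.59 in upf1 with DMSO, with CHX effects smaller by -1.70 and -1.84 in upf1. R0020C was higher by 1.26 and 0.82, and R0030W by 1.30 after CHX, with 0.34 in upf1 (adjusted p = 0.105). Of 14 pseudogenes 9 were higher in upf1 with DMSO, with a median of 1.75 (camera adjusted p = 0.0354, and 0.204 with an estimated correlation), among them AAD6 (2.60), SDC25 (2.48), FLO8 (1.81) and CRS5 (1.12). Their median difference of CHX effects was -1.23, with 8 smaller in upf1. Short RNAs such as tRNAs, of which 59 of 283 were lower in upf1 with DMSO, are captured poorly by such libraries.

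The rise of nearly all polymerase II transcripts against the snoRNAs after CHX in WT was weighed. Lower snoRNA levels or recovery would raise other stable RNAs with mRNAs, but mitochondrial mRNAs shifted by 0.22 and snRNAs by 0.079, against 1.55 for protein-coding genes, unless these RNAs were lost together with snoRNAs, which was not tested. As the whole cause, a uniform background such as DNA would give every nuclear feature of at least 500 nt the density gain of XUTs. The 5th percentile of gains over 8685 such features was 0.280 of the median XUT gain. A smaller background as part of the XUT rise is not excluded by this. The median XUT gain in replicate 1 was 0.05675, where the median XUT density in WT with DMSO was 0.0113. Decay coupled to translation and blocked by CHX may contribute, and the planned test left it open. In separate libraries the mRNAs with the largest upf1 effects rose by 0.46 more with CHX than those with the smallest at equal level (0.137 to 0.954 over bins of density), short of the 0.5 set for it and above the bound set against it.

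The dependence of both rises on RNA level was weighed with random lists of protein-coding genes matched on mean density. That abundant mRNAs rose less after CHX whatever their function may account for the ribosomal proteins (0.11 above matched lists) and translation factors (0.085 above), both inside the range of matched lists. It leaves the Hsf1 targets (-0.65 against matched lists), glycolysis (-0.50) and respiration (-0.32) lower than their level alone would place them. That low RNAs rose more whatever their class leaves XUTs 0.21 above matched mRNAs after CHX in WT, barely beyond a margin of 0.2 that was set with the trend known. The median was 1.55 over mRNAs and 1.82 in matched lists, so level may account for part of the excess of XUTs. By deciles of mean density, XUT medians were 2.18, 2.318 and 2.415 in deciles 4 to 6, against 1.824, 1.809 and 1.817 for mRNAs. In deciles 1 to 3 they were 1.508, 1.788 and 1.948, against 1.307, 1.861 and 1.975. The mean density used for matching includes the libraries with CHX and without Upf1, so it is not independent of the rises. In upf1 with DMSO XUTs stood 0.47 above matched mRNAs, from a limited pool of low mRNAs.

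Against matched lists after CHX in WT and in upf1 with DMSO, other medians differed by 0.15 and 0.59 for SUTs, -0.08 and -0.30 for CUTs, 0.14 and 0.04 for NUTs, 0.35 and 0.96 for NMD targets, 0.38 and 0.75 for meiosis genes, 0.87 and -0.55 for phosphate genes, 1.09 and -0.13 for histones, 0.35 and -0.01 for stress genes, and 0.39 and -0.05 for G2/M and M/G1 genes.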
